A study of Mus musculus with 2 samples.

How the data were processed

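Visium spatial transcriptomes of 2 tongue sections from mice treated with 4NQO were used, 1 WT section and 1 H3K36M section, with groups taken from the sample titles. Per the labels' protocols, frozen sections were fixed and permeabilised, cDNA was made in place and libraries were read in pairs. Per the submitters' processing notes, Space Ranger was used with the mouse build GRCm38 (mm10). Its version, the annotation and the clustering settings are not given in the sources used here.

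The deposited metrics table gives counts of spots, reads and detected genes per section. It also gives signal values per spot (mean reads, median genes and median UMIs, per the file headers) and each quality measure as a fraction of reads, bases or spots, as deposited, which is printed here as a percent. The deposited cluster tables give, per the file headers, an average per cluster (a signal that is never negative), a log2 fold change and a p-value for each listed gene. The file headers name neither the spots a deposited log2 fold change refers to nor whether a deposited p-value is adjusted. No test of spots was run here, since spots of a section are not replicates.

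The unit of the averages was worked out from the values. In each cluster, all averages were whole multiples of a single step (100% of values within 0.01), as UMI counts divided by the summed size factors of the cluster would be. The deposited log2 fold change equalled log2 of the ratio of the cluster to all other clustered spots, with 1 UMI added to the summed counts and 1 to the summed size factors of each side. This fixed the number of UMIs behind each average. The smallest multiple of 0.5 that made every cluster's total UMIs whole was 5027 in the WT section and 1380.5 in the H3K36M section, and was read as the median UMI count of the clustered spots. The deposited metrics give medians of 4899 and 763.5, so the clustered spots were not the set of spots behind the metrics, or the metrics came from another run. The H3K36M clusters held 1.59 times the UMIs expected from its reads under tissue, so some clustered spots may lie outside the tissue of the metrics. Cluster totals and rates rest on this reading.

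Rates are UMIs of a gene per 10000 UMIs of a cluster or section, with exact Poisson intervals at 95%. Ratios of rates have exact conditional intervals. All of these cover counting error only. The recovery and the intervals were tested on simulated tables made from the real totals. All counts were recovered in both, and intervals held the true 4-fold ratio for 99.0% of 100 changed genes in the WT simulation and 98.6% of 74 in the H3K36M simulation. The simulated tables used the same formula and Poisson counts, without spread between spots or clusters drawn from the counts. They check the calculation, not the reading of the deposited averages.

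Before the data were examined, 23 gene lists were fixed for epithelial states, other cell types of the tongue and general programmes. For each list and cluster, members higher and lower at a deposited p-value under 0.05 were counted. The median log2 fold change was placed among 10000 random lists of the same size matched on tertiles of mean expression, as a description of that section. Genes were named by a rule fixed at the same time. It took the leading genes of each cluster by positive fold change at that threshold (10 per WT cluster, 8 per H3K36M cluster, without predicted genes), up to 4 members per list in the cluster of its highest median, Krt14, and list members past the threshold in both tables. Clusters were compared by genes shared at a log2 fold change of at least 1 and by correlation across the 284 genes in both tables. Genes named outside this rule, such as Tgm1, Gstm1, H3f3a and H3f3b, were chosen after their values were seen, as were the counts of ribosomal protein genes among shared genes and of lists matched between sections.

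The design planned no fold between sections, since the tables were scaled separately. Section ratios are therefore given only in the closing observations, and were chosen after the data were seen. Alternatives were a deposited p-value under 0.01, a minimum fold, a minimum average, unmatched random lists, members in both tables only, other thresholds for shared genes, and, added later, other denominators and pairs of clusters. Gene positions came from GENCODE on GRCm38. All 879 identifiers matched it, 872 with the same symbol. Calculations used Python 3.11 with numpy, pandas, scipy and matplotlib.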

Results

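Spatial transcriptomes were recorded from mouse tongue after treatment with 4NQO, a chemical carcinogen that induces lesions of the oral epithelium. Frozen sections were placed on arrays of barcoded spots, so that each transcript molecule, counted by its unique molecular identifier (UMI), was assigned to a position in the tissue. One section came from a mouse without Cre (WT) and 1 from a mouse in which Cre under the Krt14 promoter switched on H3K36M, a mutant histone H3 that blocks methylation of lysine 36 (H3K36M). With 1 section per genotype, no spread between animals could be estimated and no test between genotypes was possible. Intervals in parentheses are 95% intervals that cover counting error only.

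The H3K36M section was much shallower than the WT section. Tissue covered 364 of 4992 spots (7.29%) in the WT section and 252 of 4992 spots (5.05%) in the H3K36M section. Total reads were 37219042 and 29810232. The median UMI count per spot under tissue was 4899 in the WT section and 763.5 in the H3K36M section, and the median number of genes per spot was 1919.5 and 596.5. The deposited fraction of reads in spots under tissue was 36.2% in the WT section and 6.93% in the H3K36M section. Mean reads under tissue per spot times spots gave 12954435 and 2036773 reads, which are smaller shares of the total reads. The base of the fraction may therefore not be total reads. Sequencing saturation was 73.0% and 79.3%, so the lower UMI count of the H3K36M section did not go with lower saturation. In all, 15690 genes were detected in the WT section and 13359 in the H3K36M section.

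Spots of the WT section had been grouped into 3 clusters and spots of the H3K36M section into 4, and each deposited table gave the average of a gene in each cluster and its fold change in that cluster. The clusters held 856199, 1354340 and 72775 UMIs in the WT section, and 17291, 306551, 193928 and 53037 UMIs in the H3K36M section. The WT table listed 865 genes, and 298 genes were listed for the H3K36M section. Both listed only genes with an average of at least 1 in some cluster, which stood for 1.99 UMIs per 10000 in the WT section and 7.24 UMIs per 10000 in the H3K36M section. Low genes therefore had less chance to be listed for the H3K36M section.

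Krt14, the keratin of basal epithelial cells whose promoter drives Cre here, was detected in every cluster of both sections. It lies on chromosome 11 from 100203162 to 100207548 on the minus strand (GRCm38). In the WT section its rate was 82.3 UMIs per 10000 (80.3 to 84.2) in cluster 1, 92.8 (91.2 to 94.5) in cluster 2 and 73.9 (67.8 to 80.4) in cluster 3. In the H3K36M section it was 42.8 (33.6 to 53.7), 44.8 (42.4 to 47.2) and 46.4 (43.4 to 49.5) in clusters 1 to 3, and 107.8 (99.2 to 117) in cluster 4. Krt14 was thus highest in cluster 4 within the H3K36M section, with a log2 fold change of 1.22 in the authors' deposited table. The mutant histone transcript itself was not analysed here.

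Within the WT section, cluster 1 was a cornified region with hair-type keratins, cluster 2 a region with higher basal keratins and cluster 3 a small region with muscle transcripts. In cluster 1 the 10 leading genes were hair keratins (Krt86, Krt81, Krt83, Krt34) and keratin-associated proteins, with log2 fold changes from 3.68 (Krt34) to 5.24 (Krtap9-1) in the authors' deposited table. Cluster 2 was led by Mir205hg, the ferritin light chain gene Ftl1 and the interferon-induced Ifitm3, with log2 fold changes of 1.99, 1.96 and 1.92 in the authors' deposited table. Cluster 3 was led by Spink12 at 4.31, Lyg1 at 2.48 and the muscle filament gene Des at 2.32 in the authors' deposited table. The numbers of genes higher and lower at a deposited p-value under 0.05 were 287 and 378 in cluster 1, 372 and 299 in cluster 2, and 34 and 13 in cluster 3, per the authors' deposited table.

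Genes of keratinocyte maturation were higher in WT cluster 1. Of the 17 listed genes of differentiated squamous epithelium, 13 were higher and 2 lower, among them Krt76 at 2.53, Krt36 at 2.11 and Lor, the major cornified envelope protein loricrin, at 1.87 in the authors' deposited table. The median of this list was 0.57, at percentile 98.1 of random lists of the same size and expression. Stress keratin and cornified envelope genes were higher in 11 of 12 cases, with Sprr1a at 1.76 and Sprr3 at 1.35 in the authors' deposited table, and Krt17 was the 1 lower member. All 10 listed keratin-associated protein genes, all 18 late cornified envelope genes and all 11 small proline-rich genes were higher in cluster 1, families grouped after their values were seen. Their members have near-identical copies, and the values of single members are uncertain for that reason.

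Basal keratinocyte and ribosomal protein genes were higher in WT cluster 2. Krt15 and Krt5, keratins of basal cells, had log2 fold changes of 1.71 and 1.18, and the basal regulator Trp63 had 0.90, in the authors' deposited table. Of the 8 listed basal keratinocyte genes, 6 were higher and 1 lower, and the list median of 0.84 stood at percentile 99.8 of matched random lists. Both listed genes of macrophages and antigen presentation, Cd74 at 1.24 and H2-Ab1 at 0.78 in the authors' deposited table, were higher in the same cluster, with a list median of 1.01. Of 81 ribosomal protein genes, 80 were higher in cluster 2. The proliferation list had 3 listed members, H2afz, Tubb5 and Hmgb2, and all 3 were higher in cluster 2, at percentile 96.9, within the central 95% of random lists. The glycolysis list had 6 of 10 members higher and 1 lower there, with Eno1 at 1.14 and the glucose transporter gene Slc2a1 at 0.95 in the authors' deposited table, but its median stood at percentile 71.3, within the range of random lists.

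Skeletal muscle genes marked WT cluster 3. Of 13 listed muscle genes, 8 were higher and 0 lower, with Des at 2.32, the calcium pump gene Atp2a1 at 1.64 and the creatine kinase gene Ckm at 1.55 in the authors' deposited table. Des rested on 16 UMIs in this cluster and Ckm on 57. Mitochondrially encoded genes were higher in 6 of 9 cases. These p-values compare spots of 1 section, which are not replicates, and the deposited header did not say whether they were adjusted. In both sections the clusters had been drawn from the same counts. Neither these p-values nor the percentiles of list medians allow for that.

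Within the H3K36M section, cluster 3 was a differentiated squamous region, and cluster 2 had higher alarmin and mitochondrial transcripts than the rest of the section. Cluster 4 was led by Ltf, Krt19, Ppbp and Psca, and cluster 1 was small with muscle transcripts. Cluster 4 had Ltf, which encodes the secreted iron-binding protein lactoferrin, at a log2 fold change of 5.12 in the authors' deposited table. Krt19 and Krt7, keratins of simple and ductal epithelia, stood at 5.09 and 4.84, and the surface antigen gene Psca at 4.95, in the authors' deposited table. Genes higher and lower at a deposited p-value under 0.05 numbered 13 and 19 in cluster 1, 101 and 91 in cluster 2, 70 and 103 in cluster 3, and 55 and 108 in cluster 4, per the authors' deposited table.

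The leading genes of cluster 4 rested on modest counts, most of them in that cluster. Ltf (chromosome 9, 111019271 to 111042767, GRCm38) had 211 UMIs in cluster 4 and 57 in the other clusters together, a ratio of rates of 36.1 (26.9 to 49.3). Psca had 106 against 32 UMIs, a ratio of 32.3 (21.6 to 49.6). Krt7 (chromosome 15, 101411043 to 101430313) had 74 against 24, a ratio of 30.1 (18.8 to 49.9), and Krt19 (chromosome 11, 100140810 to 100148665) had 49 against 13, a ratio of 36.8 (19.7 to 73.9). The chemokine gene Ppbp, the calcitonin-related gene Calcb, the retinoic acid-producing enzyme gene Aldh1a3 and the stress regulator gene Nupr1 completed the 8 leading genes, with ratios of 35.3, 31.9, 27.3 and 18.7. Of the 17 genes of the simple or ductal epithelium list, 3 were listed (Krt7, Krt19 and the tight junction gene Cldn4). All 3 were higher in cluster 4, with a list median of 4.84, the value of Krt7. Together they took 0.0636%, 0.0166% and 0.0201% of UMIs in clusters 1 to 3, below the listing limit of 7.24 UMIs per 10000. They were thus listed through cluster 4 alone, and that they were highest there was fixed by the listing. The clusters had been drawn from the same counts, which the intervals of these ratios do not allow for.

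Squamous differentiation genes were low in the same cluster. Of the 15 listed differentiated squamous genes, 12 were lower and 0 higher in cluster 4, with a median log2 fold change of -2.12. Lor had a rate of 5.09 UMIs per 10000 (3.35 to 7.41) there against 101 (96.8 to 106) in cluster 3. Krt13, the main keratin of the suprabasal tongue surface, had 73.2 (66.1 to 80.8) against 406 (397 to 415). Krt5 did not follow Krt14, at 24.5 (20.5 to 29.1) in cluster 4 against 25.9 (24.2 to 27.8) in cluster 2. All 9 mitochondrially encoded genes and 30 of 75 ribosomal protein genes were also lower in cluster 4. The ribosomal median of -0.62 stood at percentile 7.32, within the range of random lists. Of all 298 listed genes, 108 were lower in this cluster. Of the salivary gland secretory list, Ltf was the 1 gene of 23 in the H3K36M table, and none of the 23 was in the WT table.

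**Figure D1:**
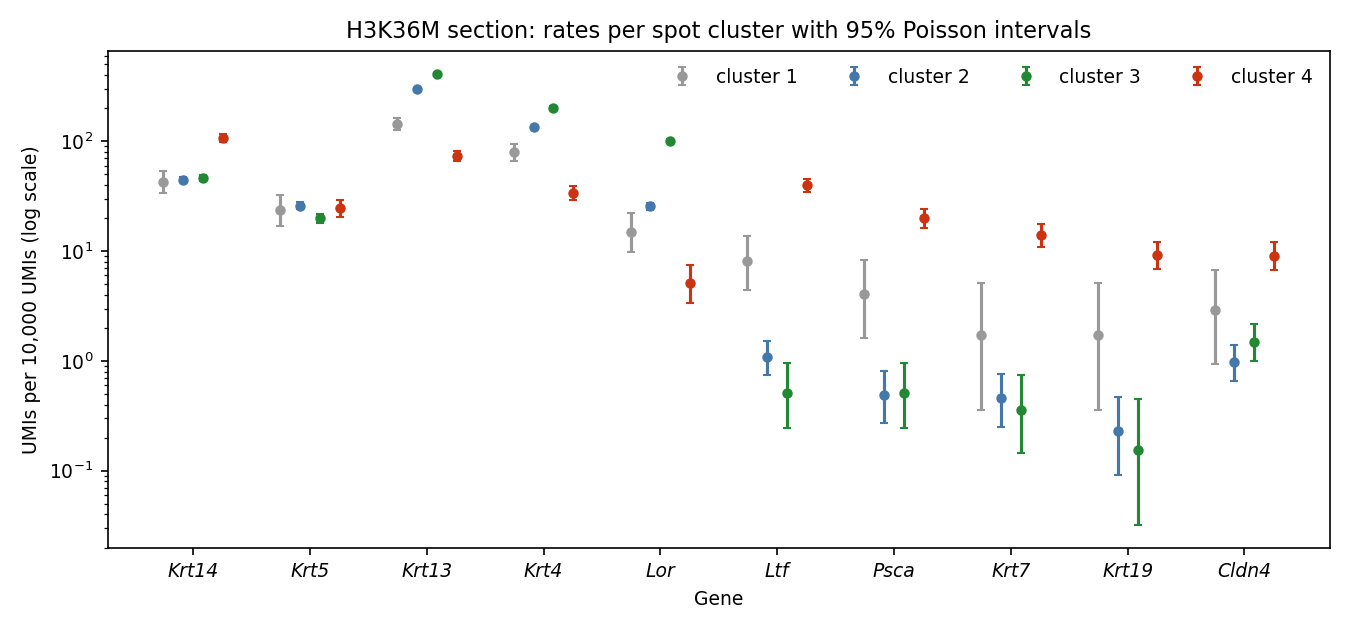
Rates of 10 genes in the 4 spot clusters of the H3K36M section, in UMIs per 10000 UMIs on a log axis, with points for the rates and bars for 95% Poisson intervals. Ltf, Psca, Krt7, Krt19, Cldn4 and Krt14 were highest in cluster 4, where Krt13, Krt4 and Lor were lowest.

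Cluster 3 of the H3K36M section carried the squamous programme. All 15 listed differentiated squamous genes were higher there, led by Krt76 at 3.94, Krt36 at 3.73 and Krt84 at 3.30 in the authors' deposited table. Of the section's UMIs of Krt76, Krt36 and Krt84, 150 of 168, 395 of 452 and 207 of 247 lay in cluster 3. In cluster 2 their rates, 0.424, 1.73 and 1.30 UMIs per 10000, were below the listing limit of 7.24. These 3 genes were thus listed through cluster 3, and that they were highest there was fixed by the listing. Fetub, Lyg1 and the cornified envelope genes Rptn and Tchh were also among the 8 leading genes of cluster 3. Cluster 2 was led by S100a9 and S100a8, subunits of the alarmin calprotectin, at 3.83 and 3.50 in the authors' deposited table. Their rates there were 17.1 and 26.5 UMIs per 10000, against 0.619 and 1.44 in cluster 3. All 9 mitochondrially encoded genes were higher in cluster 2, with a median of 2.29, as were 55 of 75 ribosomal protein genes and 6 of 11 muscle genes. Cluster 1 was led by Ikbkb at 2.69 and the class I antigen gene H2-K1 at 2.07 in the authors' deposited table, and 6 of 11 muscle genes were higher there. Its 17291 UMIs left Ikbkb with 21 UMIs and H2-K1 with 53.

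**Figure D2:**
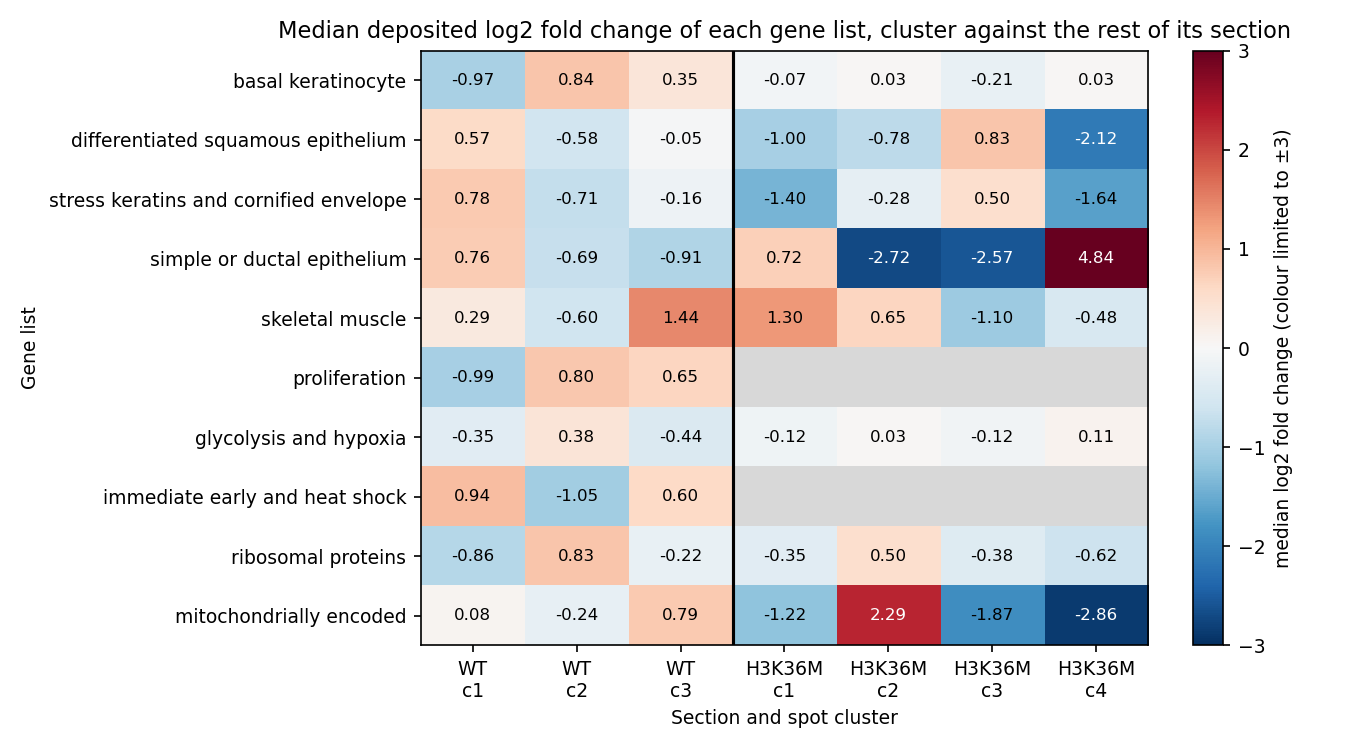
Median log2 fold change of each gene list (rows) in each spot cluster (columns) of both sections, against the rest of the same section, from the authors' deposited tables. Lists with under 3 members in a table are grey. The simple or ductal list stands at 4.84 in H3K36M cluster 4, the only cluster where its 3 listed genes could pass the listing limit.

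The clusters of both sections were set side by side over the 284 genes in both tables, to ask which regions recurred. WT cluster 1 and H3K36M cluster 3 shared 36 genes with a log2 fold change of at least 1, where independent lists would share 6.96. The shared genes included Krt76, Krt36, Krt84, Lor, Rptn and Tgm1, the enzyme that cross-links the cornified envelope. Across these 284 genes, which are not independent replicates, the fold changes of the pair had a Spearman correlation of 0.46 and a Pearson correlation of 0.60. WT cluster 2 and H3K36M cluster 2 had a Spearman correlation of 0.52 but shared 1 gene, Gstm1, against 2.02 for independent lists. At a log2 fold change of at least 0.5 the pair shared 50 genes, 36 of them ribosomal protein genes, against 35.2 for independent lists. Over the 189 genes left without ribosomal, mitochondrially encoded and muscle genes, the Spearman correlation of the pair was 0.62. WT cluster 2 and H3K36M cluster 4 had 0.45 over the same genes. Of the 8 lists with at least 3 members in both tables, 3 had their highest median in corresponding clusters, with WT clusters 1 and 2 matched to H3K36M clusters 3 and 2. These were the differentiated squamous, stress keratin and ribosomal protein lists. The clusters had been matched on the same 284 genes, which include members of these lists, so this count is no separate evidence for the match. The stress match held by its median alone, since in H3K36M cluster 3 the list had 5 members higher and 2 lower, S100a8 and S100a9, both higher in WT cluster 1. Its percentile there, 97.1, was within the central 95% of random lists. The muscle list was highest in WT cluster 3 and H3K36M cluster 1, which shared 3 genes (Atp2a1, Mb and Tnnc2) against 0.380 for independent lists. WT cluster 3 also shared 4 genes with H3K36M cluster 2 (Acta1, Ckm, Tnnc2 and mt-Nd4), against 1.06. With H3K36M cluster 3 it shared 3 (Krt76, Lyg1 and Tchh), against 1.82. Its Spearman correlation was highest there, at 0.12, against 0.08 with cluster 1 and -0.12 with cluster 2. Muscle genes were therefore not the only ones that WT cluster 3 had in common with the H3K36M section.

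H3K36M cluster 4 shared few genes with any WT cluster. It shared 7 with WT cluster 1 against 5.51 for independent lists (Aldh1a3, Arg1, Cldn4, Dusp1, Ecm1, Emp1 and Ier3), 1 with WT cluster 2 against 2.75 (Ftl1), and 0 with WT cluster 3. Its Spearman correlations were -0.31 with WT cluster 1 and 0.30 with WT cluster 2. WT clusters 1 and 2 held most WT UMIs, so their fold changes nearly mirror each other, and correlations with both are close to 1 value with opposite signs, here as for the pairs above. Of the 8 leading genes of cluster 4, Aldh1a3 was listed in the WT table, at 1.67 in cluster 1 of the authors' deposited table, where Cldn4 stood at 1.14. Ltf, Psca, Krt7 and Krt19 were not listed in the WT table. Their cluster 4 rates, from 9.24 UMIs per 10000 for Krt19 to 39.8 for Ltf, lay above the listing limit of the WT table, 1.99 UMIs per 10000. That comparison holds only if the WT table lists every gene above its limit, which could not be checked.

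**Figure D3:**
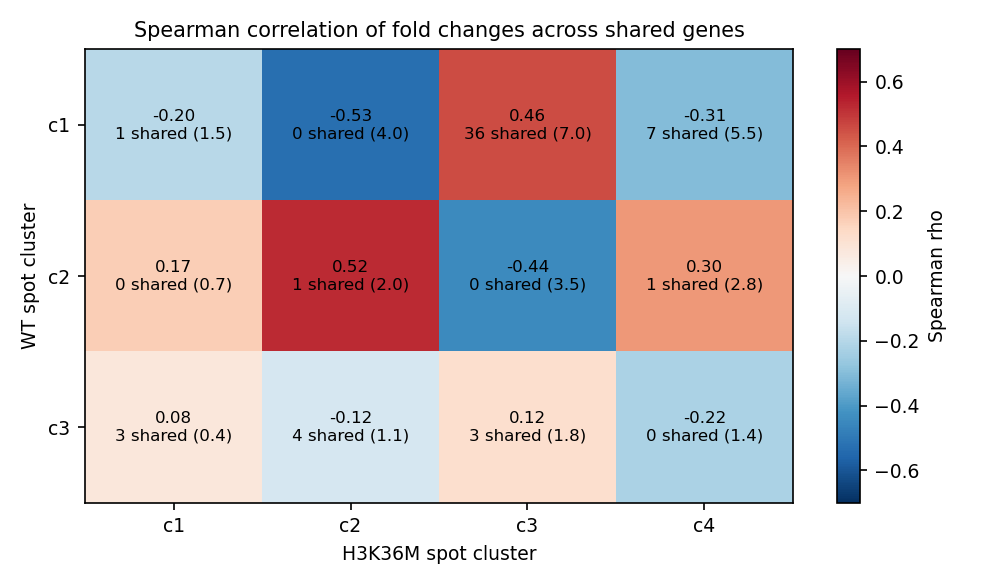
Spearman correlation of deposited log2 fold changes over the 284 genes in both tables, for each WT cluster (rows) and H3K36M cluster (columns), with the number of shared genes at a log2 fold change of at least 1 and, in parentheses, the number for independent lists. WT cluster 1 and H3K36M cluster 3 stand out with 36 shared genes.

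Rates in the whole sections were placed side by side for the gene lists, as values of 1 section each. Stress keratin and cornified envelope genes took 7.79% of the WT UMIs and 2.42% of the H3K36M UMIs over the 9 members in both tables. Differentiated squamous genes took 8.01% and 7.30%, and the 3 basal genes Krt14, Krt5 and Krt15 took 1.20% and 0.911%. Skeletal muscle genes took 0.279% and 0.716%, and mitochondrially encoded genes 2.01% and 3.84%. The mitochondrial excess came from H3K36M cluster 2, at 6.09%, while clusters 1, 3 and 4 had 1.54%, 1.38% and 0.609%, below the 2.03%, 1.93% and 3.19% of WT clusters 1 to 3. S100a8 had 170 UMIs per 10000 (168 to 172) in the WT section and 15.3 (14.3 to 16.4) in the H3K36M section. Krt17 had 55.9 (55.0 to 56.9) and 17.8 (16.7 to 18.9), while Krt13 had 324 (321 to 326) and 309 (304 to 313). Both muscle and mitochondrial transcripts differed along with the keratins, and depth, tissue sampled and genotype all differed between the 2 sections.

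**Figure D4:**
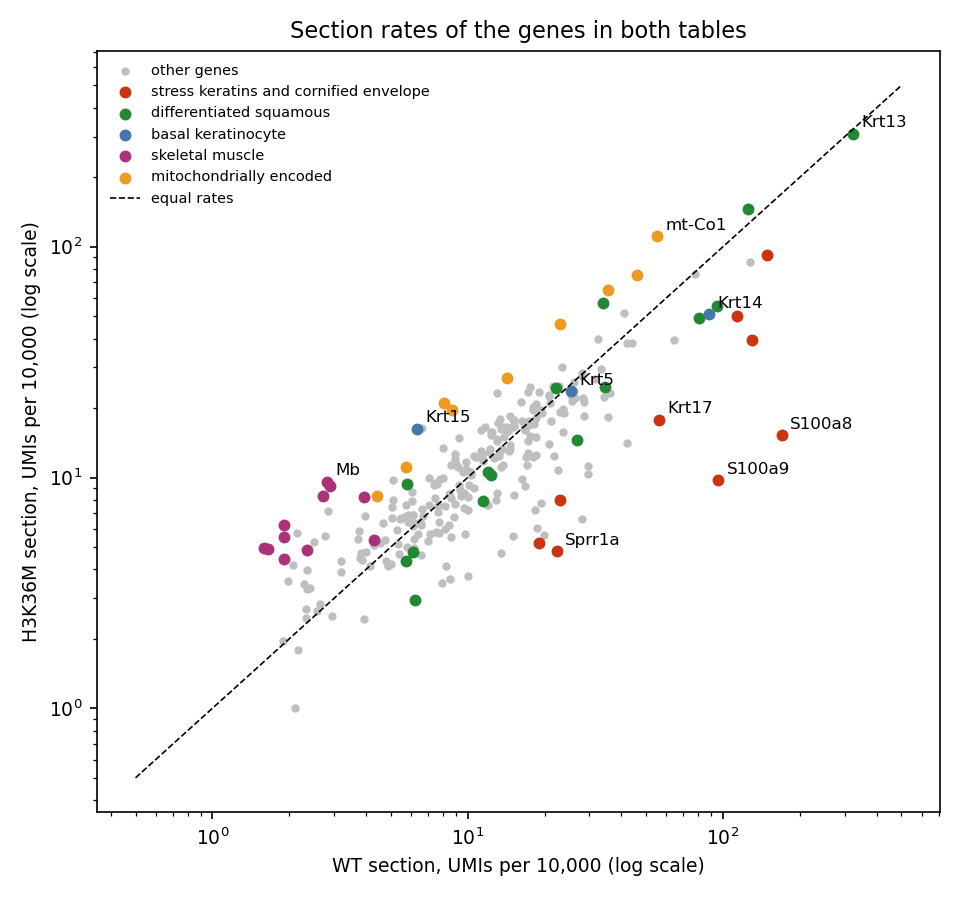
Rate of each of the 284 genes in both tables in the WT section (horizontal) and the H3K36M section (vertical), in UMIs per 10000 UMIs on log axes, with 5 gene lists in colour and the line of equal rates dashed. The stress keratin and cornified envelope genes lie below the line, and the muscle and mitochondrially encoded genes above it, the latter through H3K36M cluster 2.

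Immune and stromal genes were mostly outside both tables. Members listed were Cd74 and H2-Ab1 for the macrophage and antigen presentation list, Cd44 for the invasion list and Elovl4 for the lipid synthesis list, each in the WT table. The neutrophil list was represented by S100a8 and S100a9, which the stress list also holds and keratinocytes also express. The lists for fibroblasts, endothelial cells, lymphocytes, erythroid cells, interferon response, Schwann cells and adipocytes had 0 members in either table. Of the immediate early and heat shock list, the WT table held 5 members, with Dusp1 at 1.24 and Jun at 1.22 in cluster 1 of the authors' deposited table, and the H3K36M table held Dusp1, at 2.05 in cluster 4 of the authors' deposited table. Of the H3K36 and H3K27 methylation enzyme list, only the histone genes H3f3a and H3f3b were listed.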

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

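In the H3K36M section, 93.1% of reads lay in spots outside tissue, against 63.8% in the WT section. The value stands here because the reads counted as outside tissue are not themselves measured in the report. Whether some of them enter the cluster tables is open. The clusters of the H3K36M section held 570807 UMIs, 1.59 times the 358413 expected from the reads under tissue, the share mapped to the transcriptome and the saturation of the section. In the WT section that ratio was 0.786. The cause of the high share was not tested, and no biological explanation was tested.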

How the results depend on the processing

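Settings added after seeing the data are the section ratios, their denominators and pairs of clusters, and the removal of clusters with under 5% of UMIs. Requiring an absolute log2 fold change of at least 1 gave 249, 238 and 31 genes in WT clusters 1 to 3 and 78 and 82 in H3K36M clusters 2 and 3, fewer by construction. A deposited p-value under 0.01 left 15 genes in H3K36M cluster 1. Over genes in both tables, 8 of 21 list and cluster pairs of the WT section lay outside the central 95% of random lists, against 14 of 30 with every listed gene. WT cluster 2 and H3K36M cluster 2 shared 50 genes at a log2 fold change of 0.5 and 13 among the top 50 genes, against 35.2 and 8.80 for independent lists. WT cluster 2 and H3K36M cluster 4 shared 16 and 5, and 3 without the small clusters, each below the 19.8, 8.80 and 4.06 of independent lists. WT cluster 1 and H3K36M cluster 3 shared 36 to 48 genes in all settings run, among them at least 35 of the 36 shared in the first setting. For section ratios within WT cluster 1 and H3K36M cluster 3, the log2 median was -0.052 for differentiated squamous, 0.45 for muscle and 0.36 for ribosomal genes, and it reversed to -0.55 for mitochondrially encoded genes, as did Krt5 to 0.58. There S100a8 stood at -7.13 and Krt15 at 2.65. Within cluster 2 of both, it was 2.07 for muscle and 1.67 for mitochondrially encoded genes, and ribosomal genes reversed to -0.0027 from 0.02, with S100a8 at -2.54, Krt15 at 0.90 and Krt14 at -1.05. The cause was not tested. Depth limits the H3K36M section, where cluster 1 held 17291 UMIs. No paired analysis was possible because each genotype had 1 section.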

Other observations

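All section ratios and tests in this part were chosen after the data had been seen, and only for the removal of mitochondrially encoded or muscle UMIs was the outcome each explanation needs set before its value was computed. Those UMIs were too few for either removal to have come out otherwise. Over the 284 genes in both tables, the median log2 ratio of H3K36M to WT rates was 0.01. Of these genes, 106 had a ratio with an interval below 1 and 117 had one above 1. The log2 ratio was at most -1 for 24 genes and at least 1 for 20. The 9 stress keratin and cornified envelope genes were lower in 9 of 9 cases, with a median of -1.73. Genes off this list fell as far, such as Serpinb3a at -2.08 and Lce3f at -1.82, picked out after their values were seen. S100a8 was 11.1-fold lower (10.4 to 11.9), S100a9 9.83-fold lower (9.04 to 10.7) and Krt17 3.14-fold lower (2.94 to 3.35) in the H3K36M section. The size moved with the clusters compared. Between WT cluster 1 and H3K36M cluster 3, S100a8 was 140-fold, S100a9 188-fold and Krt17 2.22-fold lower, and between cluster 2 of both they were 5.80-fold, 4.93-fold and 4.68-fold lower. The first pair rests on 28 UMIs of S100a8 and 12 of S100a9 in the H3K36M cluster. Krt15, by contrast, was higher at a log2 ratio of 1.37 (2.65 and 0.90 in these pairs), while Krt14 was lower at -0.79 (-0.83 and -1.05). The 11 muscle genes were higher in 11 of 11 cases, with a median of 1.57. In the same pairs their median was 0.45 and 2.07, and in the first of them the intervals of Myh4, at a ratio of 0.827 (0.633 to 1.07), Tpm2, Tpm1, Tnnc2 and Mylpf span 1. These intervals compare 2 sections, not genotypes.

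Anxa1, which encodes the phospholipid-binding protein annexin A1 and was picked out after its values were seen, had 84.7 UMIs per 10000 (77.0 to 92.9) in H3K36M cluster 4 and 4.18 (3.32 to 5.19) in cluster 3. In the WT section it had 46.7 in cluster 1, 40.3 in cluster 2 and 16.8 in cluster 3. Sprr2i, Sprr2d and the gap junction gene Gjb2, picked out in the same way, were listed in the WT table alone, at 39.2, 31.2 and 23.3 UMIs per 10000 in cluster 1, above the H3K36M listing limit of 7.24. In all, 41 of the 581 genes in the WT table alone reached that limit, 29 of them with a lower bound above it, and 14 genes were in the H3K36M table alone. This comparison holds only if the H3K36M table lists every gene above its limit, which could not be checked.

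What tissue the leading genes of H3K36M cluster 4 mark was not settled, with 2 of the 8 (Krt7 and Krt19) on the simple or ductal list and 1 (Ltf) on the salivary list. Mitochondrially encoded UMIs made up 0.609% of cluster 4 and 3.84% of the section, too few for their lack to raise other genes by much. Without them the median log2 fold change of the 8 leading genes went from 4.92 to 4.87. Every gene moves alike under this removal, so it was no test of these genes. Counting noise was first tried on the leading genes, where the lowest lower bound of the ratio was 12.2, but these genes had been chosen for high ratios and the value decides nothing. A replacement, set after that value was seen, used all 298 genes with bounds corrected for their number, and 25 had a ratio with a lower bound above 2, but the clusters were drawn from the same counts, so this does not exclude noise either. Normal salivary gland under these spots cannot be told apart from a changed epithelium, since 1 salivary list member was in the table and a gene missing from the table excludes nothing, and the genotype remains untested.

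The lower stress keratin rates of the H3K36M section could reflect dilution by other tissue, but the stress list lay -1.41 below the basal and differentiated lists in median log2 ratio. Without mitochondrially encoded and muscle UMIs the stress median was -1.69, against -1.73 with all UMIs. Members of these 2 lists in both tables took 2.01% and 0.279% of WT UMIs and 3.84% and 0.716% of H3K36M UMIs. Shares of this size are too small to give the fall, and their removal shifts every gene alike, so the value was fixed by the totals. A different share of regions also leaves the stress list lower, since the smaller fall within paired clusters was -1.66, and that pairing is weak for cluster 2. Without pairing, 9 of 9 members had an upper bound below the lower bound of every WT cluster, which no mixture of the 3 WT clusters gives. Finer regions within a cluster, depth, the tissue sampled, the animal and the genotype remain open, as 1 section stands for each. The set of clustered spots is open as well. The H3K36M clusters held 1.59 times the UMIs expected under tissue, against 0.786 in the WT section.

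The length of the H3K36M table goes with its depth, since 266 WT genes would pass the listing limit at the H3K36M scale, against the 298 listed. The genes differed more than the length, as 41 of the 266 were in the WT table alone. The range of lengths taken to fit was wide, so a similar length alone decides little.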
